A study of Mus musculus with 2 samples.

How the data were processed

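RNA abundance in mouse spleen was measured on 2 oligonucleotide arrays. Per the labels, both arrays started from spleen total RNA purchased under 1 catalogue number, so the arrays form 1 group of 2, named array 1 and array 2 after their titles. The labels do not say whether the arrays shared 1 tube, 1 labelling reaction or 1 day. The spread between them therefore holds technical variation of the arrays, and whether it also holds a difference between RNA lots or animals is not known. No condition was compared with another, and no p-value was computed.

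The deposited table gave 1 signal intensity per probe set and array on a linear scale, for 12488 probe sets. All values were above 0, from 0.1 to 59495.1 on array 1 and from 0.4 to 58117.2 on array 2. With the lowest and highest 2% of probe sets left out, the mean of the deposited intensities was 500.265 on array 1 and 500.278 on array 2, so both arrays had been scaled to a common target before deposit. The software that made the intensities is not given in the sources used here, and neither are detection calls. An array holds no read depth, and the number of arrays limits the precision.

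The table held 66 control probe sets, recognised by the AFFX prefix of Affymetrix arrays, and 12422 others. Controls stayed out of percentiles, lists and counts. Of the others, 10833 named a single gene in the platform's annotation, 396 named several genes and 1193 named none. Gene identifiers of 10817 of the single-gene probe sets were found in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols had to be updated. That table served for names alone, because the arrays name no genome build, and no coordinates are given. The single-gene probe sets covered 8251 genes. A gene's value was that of its single-gene probe set with the highest mean log2 signal. Of the 2073 genes with several probe sets, 383 had a bright one and another that lay at or below the highest bacterial control on both arrays.

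The following settings, the gene lists and the rule for naming genes were fixed before the data were examined. Intensities were used as deposited, floored at the 20th percentile of their own array (41.8 on both) and put on the log2 scale. A probe set was called bright when it exceeded the 60th percentile of its own array on both arrays, which was 346.32 on array 1 and 342.22 on array 2. Log2 differences are array 2 minus array 1, centred on the median over bright probe sets. The SD of a gene is that of its 2 intensities. A pooled SD was computed from the log2 differences over many probe sets.

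The 22 lists covered 10 resident or blood cell classes of the spleen, 5 cell functions and 7 other tissues, with 370 genes, of which 295 were measured by a single-gene probe set. For each list the number of bright genes was counted, and the list's median log2 signal was placed among 10000 random lists of as many genes. The median log2 difference between the arrays was placed among 10000 random lists of bright genes matched on mean signal in 20 bins, for lists with at least 3 bright genes. These percentiles describe these arrays. A probe set's brightness depends on its sequence as well as on its transcript, so single genes are not ranked against each other. Named genes were the first 3 measured members of each cell class list, the first 2 of each function list, the first 1 of each other tissue list, the 10 genes with the highest mean log2 signal, and the 5 bright genes furthest apart between the arrays in each direction. Further genes are named where a count was 5 or fewer or where a list stood out, and were chosen after their values were seen.

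The list statistics were checked on random lists. For levels, 200 lists of 15 genes were drawn from the same 8251 genes as the random lists they were placed among. The share at or above the 95th percentile, 4.5%, was therefore near nominal by construction. It was 99.5% after a shift by 3 on the log2 scale. For differences, normally distributed values were simulated for 3731 bright genes. There, 6% of unshifted lists and 100% of lists shifted by 0.3 reached the 95th percentile. That shift exceeded the median difference of every list with at least 3 bright genes, so smaller shifts were not checked. Nor were the limits of the central 95% used for list differences. Alternatives changed 1 choice at a time: the floor or a pseudocount of 16, quantile or loess normalization or no centring, other brightness cutoffs, each array alone, the mean over a gene's probe sets, probe sets marked for several targets left out, and, added after the data were seen, probe sets that name several genes. Probe sets marked for several targets are here all those with the suffix _s_at, _x_at, _f_at, _r_at, _g_at or _i_at. That setting therefore also left out _r_at probe sets, whose suffix marks relaxed probe selection. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.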

Results

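Gene expression was profiled in purchased total RNA of mouse spleen, a lymphoid organ that also filters blood and, in the mouse, makes red blood cells. The RNA was hybridised to 2 arrays of 12488 probe sets. The series names no treatment or control, so the data describe what spleen RNA contained and how closely both arrays measured it. Signal medians were 226.65 on array 1 and 226.4 on array 2. The 15 bacterial control probe sets for dap, lys, phe, thr and trp, whose targets are foreign to mouse, gave the background: their median was 20.6 on array 1 and 22.9 on array 2, and their highest value was 95 and 76.2. Above that highest value lay 67.8% of the other probe sets on array 1 and 71.3% on array 2. The ratio of 3′ to 5′ probe sets, a measure of RNA integrity and labelling length, was 1.19 and 1.22 for beta-actin and 0.965 and 0.963 for Gapdh on arrays 1 and 2. For the transferrin receptor it was 5.18 and 4.32.

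The 2 arrays gave closely matching signals. Over the 4708 probe sets that were bright on both arrays, 37.9% of the 12422, Pearson's r of the log2 signals was 0.985 and Spearman's rho was 0.966. These correlations run across probe sets, which are not independent replicates. The pooled SD was 0.152 on the log2 scale, or 11.1% of the signal, and 95% of bright probe sets differed by less than 1.36-fold. Only 6 bright probe sets differed by more than 2-fold, 2 higher on array 2 and 4 higher on array 1. Because bright probe sets passed the cutoff on both arrays, those that fell below it on 1 array were left out of these values. Probe sets were then split by mean signal into 4 groups of equal size. The pooled SD was 0.142 in the brightest group, 0.234 in the next and 0.522 in the one after. Differences of more than 2-fold were found for 3 probe sets of the brightest group, 44 of the next and 17.6% of the one after. In the dimmest group, in which the floor replaced low values, the pooled SD was 0.230. Identical values on both arrays were found for 23 probe sets, so the arrays were not 1 measurement deposited again.

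**Figure D1:**
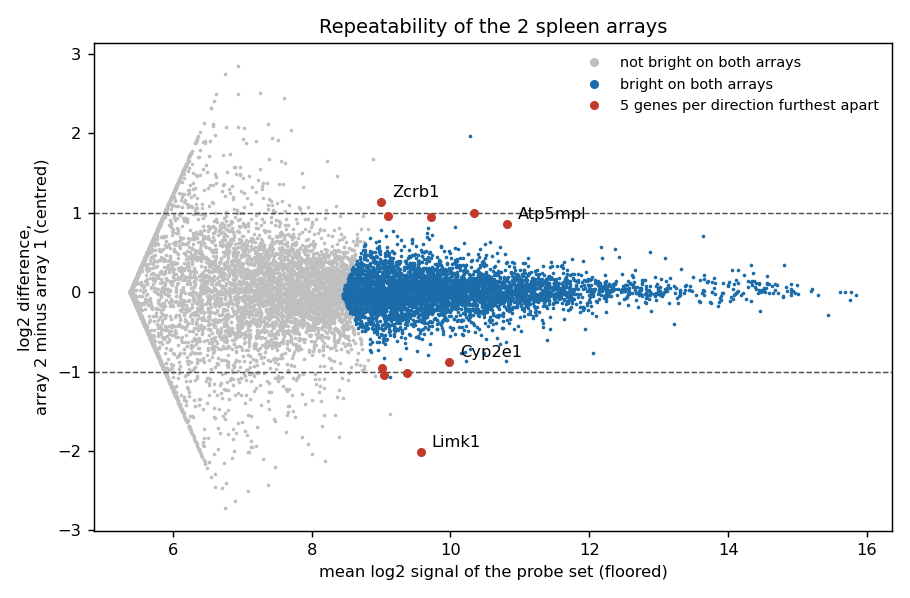
Each point is a probe set, with its mean log2 signal over both arrays on the horizontal axis and the centred log2 difference, array 2 minus array 1, on the vertical axis; dashed lines mark a 2-fold difference. Blue points are bright on both arrays, grey points are not, and red points are the 5 genes per direction that were furthest apart by their brightest single-gene probe set, so blue points beyond them are other probe sets; the pooled SD of the blue points is 0.152.

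Genes of B cells, the antibody-producing lineage, were bright as a group. Of 17 measured genes 15 were bright, against 45.2% of all 8251 named genes, and the list's median lay at the 100th percentile of random lists. Cd79a and Cd79b, the signalling chains of the B cell receptor, gave 10602 ± 380.0 and 7162 ± 98.4 (SD, n = 2 arrays here and below). Cd22, an inhibitory co-receptor, gave 1226 ± 48.3. Cr2, the complement receptor of mature B cells, at 201 ± 13.2, and Ebf1, at 371 ± 67.7 and below the cutoff on array 2, were not bright. The only single-gene probe set of Cr2 carries the suffix _r_at, which marks relaxed probe selection. All 11 measured genes of antigen presentation by MHC class II were bright, at the 100th percentile. Among them the class II chains H2-Aa and H2-Ab1 gave 25449 ± 902 and 10166 ± 218.

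T cell genes were also bright for the most part. Of 19 measured genes 16 were bright and the list's median lay at the 98.2nd percentile, or at the 94.8th without probe sets marked for several targets. With the cutoff at the 75th percentile 10 were bright, against 28.5% of all named genes. The CD3 chains of the T cell receptor complex gave 1190 ± 48.5 for Cd3e, 590.0 ± 26.3 for Cd3d and 748 ± 114 for Cd3g. The members that were not bright were Ctla4, an inhibitory receptor induced on activation, at 88.8 ± 18.8, Txk at 352 ± 39.7 and Cd28 at 373 ± 51.0. Natural killer and cytotoxic cell genes stood at the 19.97th percentile, with 3 of 12 bright. The percentile was 11.74 on array 1 alone, 22.86 on array 2 alone and 34.36 with the mean over probe sets, and 1 to 10 genes were bright under other cutoffs. These were Klrd1, a chain of natural killer receptors, at 374 ± 22.3, the protease Gzma at 457 ± 23.8, and the chemokine Ccl5, which T cells also make, at 2196 ± 133. The pore-forming Prf1, at 158 ± 18.9, was not bright. Of 10 plasma cell genes 5 were bright, at the 73.7th percentile: the joining chain of antibodies Jchain at 7612 ± 64.3, the secretory regulator Xbp1 at 2143 ± 289.8, Irf4, Creld2 and Txndc5. Sdc1, the surface marker CD138 of plasma cells, gave 91.0 ± 2.76 and was not bright.

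Macrophage and monocyte genes were bright in 16 of 19 cases, at the 100th percentile. With the mean over a gene's probe sets 10 were bright, against 35.7% of all named genes. Csf1r, the receptor on which macrophages depend, gave 3581 ± 84.8, Adgre1, which encodes F4/80, gave 463 ± 23.2, and the complement gene C1qa gave 6350 ± 193. The 3 that were not bright were Siglec1 at 34.7 ± 28.9, Marco at 348 ± 43.3 and Msr1. Siglec1 and Marco mark macrophages of the marginal zone. Of 10 dendritic cell genes 8 were bright, at the 95.4th percentile, which became the 91.2nd without probe sets marked for several targets. With the cutoff at the 75th percentile 5 were bright, against 28.5% of all named genes. Itgax, which encodes CD11c, gave 855 ± 22.98, Flt3 gave 1053 ± 101 and the transcription factor Batf3 gave 618 ± 28.001, whereas the chemokines Ccl17 and Ccl22 were not bright. Neutrophil and granulocyte precursor genes were bright in 13 of 17 cases, at the 99.8th percentile. The calcium-binding alarmins S100a8 and S100a9 gave 11078 ± 112 and 6521 ± 887, and the granule gene Ngp gave 4807 ± 277. Ctsg, Cxcr2, Mmp8 and Mmp9 were not bright.

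Genes of red blood cell formation were bright in 13 of 14 cases, at the 100th percentile. Alas2, the first enzyme of erythroid haem synthesis, gave 12732 ± 125, the erythroid transcription factor Klf1 gave 3177 ± 138, and the alpha globin Hba-a1 gave 55352 ± 2735. The globin probe sets cannot be assigned to 1 copy with certainty, because alpha and beta globin genes each have near-identical copies. Fech, the last enzyme of haem synthesis, gave 132 ± 14.5 and was not bright. Like that of Cr2, its only single-gene probe set carries the suffix _r_at. Of the cell division genes 18 of 20 were bright, at the 99.99th percentile, among them Mki67 at 2658 ± 0.919 and the topoisomerase Top2a at 848 ± 113, whereas Bub1 and Mcm6 were not. Of 5 megakaryocyte and platelet genes 2 were bright, at the 16.02nd percentile, which was 10.19 on array 1 alone and 33.72 on array 2 alone. With the mean over probe sets 1 was bright, and with the cutoff at the 75th percentile 0 were. Gp9, part of the platelet receptor for von Willebrand factor, gave 475 ± 105 and Vwf gave 647 ± 51.6. The platelet chemokine Pf4 gave 61.5 ± 20.7 and Gp5 gave 145 ± 102.

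Genes of stroma, smooth muscle and endothelium were bright in 10 of 20 cases, at the 75.5th percentile. Smooth muscle actin Acta2 gave 786 ± 0.0707 and the collagen Col3a1 gave 483 ± 119. The endothelial Pecam1 gave 76.3 on array 1 and 285.0 on array 2, a log2 difference of 1.90, and was not bright. Its mean lay in the signal range where the pooled SD was 0.522.

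Among the remaining cell functions, 9 of 13 interferon response genes were bright, at the 99.9th percentile, including the regulator Irf7 at 1310 ± 83.5 and the ubiquitin-like Isg15 at 2946 ± 13.2. Ifit1, Ifit2, Ifit3 and Mx1 were not bright, though Ifit1, at 318.8 on array 1 and 386.5 on array 2, passed the cutoff on array 2. Of 16 immediate early and heat shock genes 10 were bright, at the 94.0th percentile, while Fos and Jun, subunits of the AP-1 transcription factor, gave 223 ± 21.99 and 144 ± 1.06 and were not. Ribosomal protein genes stood at the 100th percentile, with 9 of 13 bright, including Rps3 at 22180 ± 78.4 and Rplp0 at 30656 ± 1487. The other 4, Rps14, Rps15, Rps20 and Rpl32, gave means between 15.1 and 42.7, within the range of the bacterial controls.

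The genes named by the rule on mean log2 signal are given without an order, since brightness depends on the probe sequence, and probe sets with no gene name or several were not eligible. They included Ighm, the heavy chain of IgM, at 56019 ± 137 and the kappa variable segment Igkv6-23 at 52838 ± 24.2. They also included the globins Hba-a1 and Hbb-b2, the latter at 30601 ± 526. Cd74, the invariant chain of MHC class II, gave 30771 ± 20.3. The ribosomal proteins Rpl41, Rps24 and Rplp0, the elongation factor Eef1a1 and Tpt1 completed the set, with Rpl41 at 49835 ± 35.8, Rps24 at 31868 ± 234, Eef1a1 at 40030 ± 638 and Tpt1 at 37425 ± 252. The probe sets of Igkv6-23 and Rpl41 are marked as reading families of similar sequences. That of Ighm carries the suffix _s_at and that of Rps24 the suffix _r_at.

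**Figure D2:**
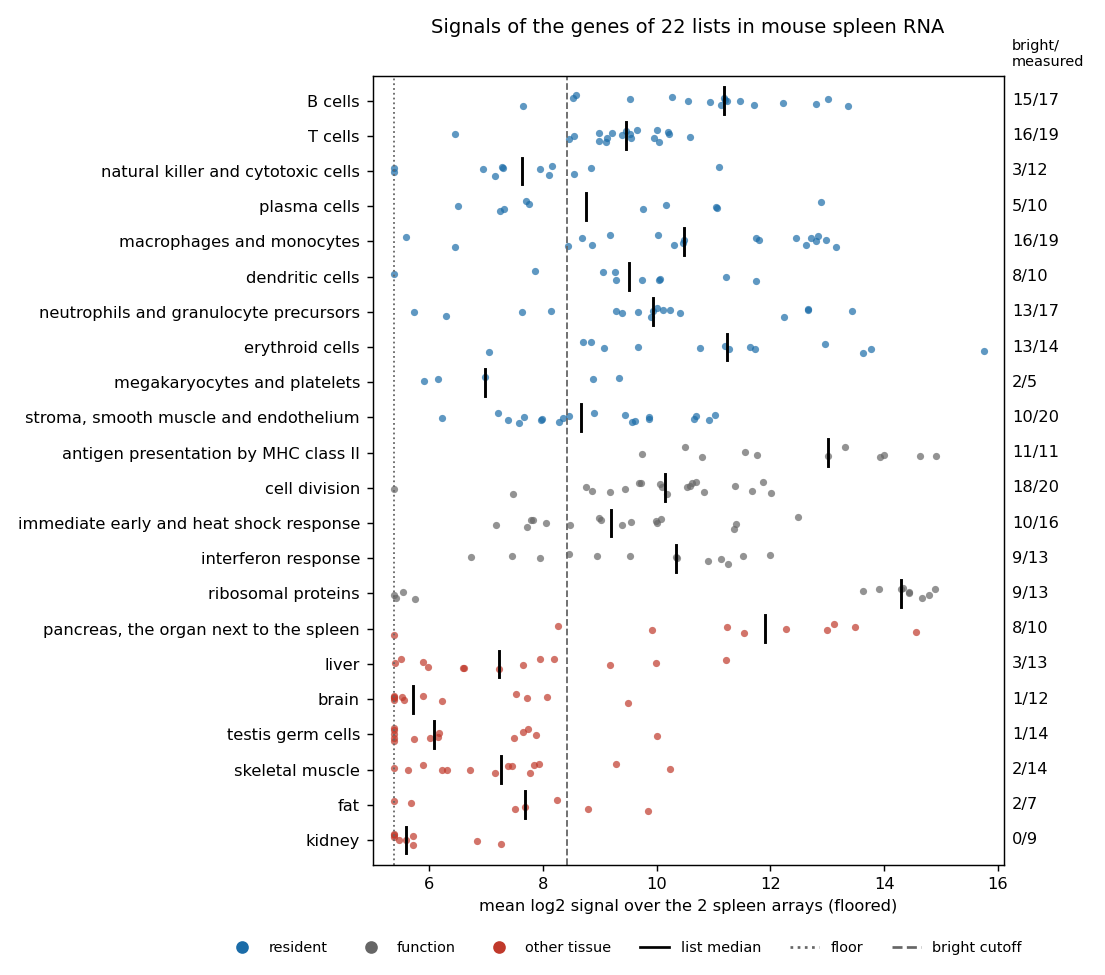
Each point is a gene, placed by its mean log2 signal over both arrays, in 1 row per list; blue points are cell classes, grey points cell functions and red points other tissues. Black bars are list medians, the dotted line is the floor, the dashed line the mean brightness cutoff, and the numbers at the right give bright over measured genes, 15 of 17 for B cells and 8 of 10 for pancreas.

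Lists of other tissues served as a background for these counts. Across liver, brain, testis germ cells, skeletal muscle, fat and kidney, 9 of 69 genes were bright. Liver stood at the 9.38th percentile with 3 of 13 bright, which were Alb, the plasma protein albumin, at 2384 ± 302, Apoa1 and Cyp2e1. Brain stood at the 0.12th percentile with 1 of 12 bright, Mbp, and its Snap25 gave 6.85 ± 0.919. Testis germ cells stood at the 0.36th percentile with 1 of 14 bright, Tnp1, while the protamine Prm1 gave 206 ± 61.9. Skeletal muscle stood at the 8.76th percentile with 2 of 14 bright, Pvalb and Eno3, and its actin Acta1 gave 79.4 ± 3.32. Fat stood at the 28.2nd percentile with 2 of 7 bright, Lep and Lpl, and Adipoq gave 304 ± 31.7. Kidney stood at the 0.275th percentile with 0 of 9 bright, and its Umod gave 7.95 ± 0.919. On arrays 1 and 2 alone the percentile was 10.955 and 6.655 for liver, 0.07 and 0.21 for brain, 0.64 and 0.22 for testis germ cells, 13.05 and 5.45 for skeletal muscle, 27.6 and 27.8 for fat, and 0.16 and 0.73 for kidney. Without probe sets marked for several targets skeletal muscle stood at 0.87, with 1 of 12 bright, and with the mean over probe sets 0 of 7 fat genes were bright.

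For the pancreas, which lies next to the spleen, 8 of 10 measured genes were bright, and the median lay at the 100th percentile. Cela1, an elastase of acinar cells, gave 8880 ± 57.6. The other bright members were Ctrb1, a chymotrypsinogen, at 24153 ± 1240, the trypsinogen Prss2 at 11435 ± 101, the lipase Cel at 8125 ± 179, colipase Clps at 4949 ± 44.1, Reg1 at 2982 ± 22.7, the lipase-related Pnliprp1 at 2409 ± 289.6 and Cela2a at 974 ± 92.3. The hormones of pancreatic islets were not bright: insulin Ins2 gave 308 ± 10.4 and glucagon Gcg gave 17.95 ± 5.02. The probe sets used for Prss2 and Ins2 are marked as reading families of similar sequences, and that of Ctrb1 carries the suffix _r_at.

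The lists were also compared between the arrays. Of the 16 lists with at least 3 bright genes, 14 had a median log2 difference between -0.12 and 0.12 and lay inside the central 95% of random lists. Of these 14, cell division and ribosomal proteins lay outside it with brightness set at the 75th percentile, at the 1.16th and 97.7th percentiles, and immediate early and heat shock genes without probe sets marked for several targets, at the 98.6th. Neutrophil and granulocyte precursor genes had a median of 0.12, with 10 of 13 bright genes higher on array 2, at the 98.6th percentile. The 3 bright liver genes had a median of 0.25 at the 98.1st percentile, with 2 higher on array 2 and Cyp2e1 higher on array 1. Chance alone would put 0.8 of 16 lists outside this range. The neutrophil list lay inside the range with loess normalization, at the 97.3rd percentile, and with no brightness filter, at the 90.7th. The liver list lay inside it without probe sets marked for several targets, at the 96.98th, and with no brightness filter, at the 66.6th, and its median turned to -0.32 with brightness set at the 75th percentile.

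Of 3731 bright genes, 3 were more than 2-fold higher on array 1 and 1 was more than 2-fold higher on array 2. Limk1, a kinase of the actin cytoskeleton, gave 1529.9 on array 1 and 377.6 on array 2, a log2 difference of -2.02. Next came Gm7775 at -1.05, the AP-1 subunit Junb at -1.01, the slow troponin Tnni1 at -0.95 and the cytochrome Cyp2e1 at -0.89. In the other direction Zcrb1 gave 347.9 and 760.1, a log2 difference of 1.13, followed by Rgs19 at 0.99, Cdk5rap3 at 0.96, Utp20 at 0.94 and Atp5mpl at 0.86. Where the mean over all of a gene's probe sets was taken, the difference shrank to -0.81 for Limk1, -0.38 for Junb, 0.27 for Rgs19 and 0.34 for Cdk5rap3. A dimmer probe set of the MHC class I gene H2-K1, singled out after its values were seen, gave 626.8 and 2455.1, a log2 difference of 1.97, while the gene's brightest probe set gave 22408.5 and 25817.5. With 2 arrays in 1 group these gaps have no test.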

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

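Probe sets without a gene name in the annotation entered no list, and they carried signal too. Of these 1193 probe sets, 564 lay above the highest bacterial control on both arrays, and 274 were bright. The brightest of them by mean log2 signal gave 31048.7 on array 1 and 31437.1 on array 2. With 2 arrays, no group was large enough for a check of single arrays that stand apart, and there was only 1 group, so no effects of groups were compared.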

How the results depend on the processing

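The agreement of the arrays depended on how dim the probe sets were. Pearson's r was 0.987 and the pooled SD 0.128 with brightness set at the 75th percentile, and 0.975 and 0.317 with no brightness filter. The number of probe sets more than 2-fold apart was then 0 and 633. The pseudocount moved none of these 3 results beyond the bootstrap interval or by over 1.5 times. That interval, 0.983 to 0.986 for r and 0.146 to 0.158 for the pooled SD, came from 1000 resamplings of bright probe sets, not of arrays. It served as a yardstick and does not measure the uncertainty of the agreement. Quantile and loess normalization and no centring, run for the pooled SD and the 2-fold count, stayed within these limits, as did controls kept, run for r. The floor at the 10th percentile, and no floor, run for r, cannot change these results by construction, because bright probe sets lie above the floor. The number of lists at or above the 95th percentile was 11 of 22 and ranged from 9 to 12 over the 8 alternatives; the 3 brightness cutoffs cannot change it by construction. The bright genes of the resident lists, 101 of 143, ranged from 77 to 129, and those of the pancreas list were 8 of 10 on each array alone and with the cutoff at the 75th percentile, 7 of 10 with the mean over probe sets, 9 of 10 with both lower cutoffs, 6 of 7 without probe sets marked for several targets and 10 of 12 with probe sets that name several genes. The bright genes of the other 6 tissue lists, 9 of 69, became 14 with brightness at the 50th percentile, 32 with the cutoff at the highest bacterial control, which 73.9% of all genes passed, and 4 with the mean over probe sets. The number of lists with an outlying difference between the arrays, 2, became 1 with loess, where the neutrophil list lay inside the range at the 97.3rd percentile and the liver list remained. It was also 1 with no brightness filter, but there the neutrophil and liver lists lay inside the range, at the 90.7th and 66.6th percentiles, and the outlying list was megakaryocytes and platelets, at the 99.1st with a median of 0.70 over 5 genes against -0.31 over its 2 bright genes. With brightness at the 75th percentile it was 3 of 14: cell division at the 1.16th percentile, and ribosomal proteins and neutrophils both at the 97.7th. Without probe sets marked for several targets it was 2 of 15, neutrophils at the 98.9th and immediate early and heat shock genes at the 98.6th. The median difference of the liver list reversed to -0.32 with brightness at the 75th percentile, where fewer of its genes were left. Leaving out 1 array was possible for levels only, since a difference needs both. No paired analysis was possible because there was only 1 group. Signal over background limits what dim probe sets can show: the pooled SD was 0.522 in the group with the next to dimmest signals, against 0.142 in the brightest group.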

Other observations

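The gene groups in this paragraph were chosen after the data were seen. Antibody genes were read by 64 single-gene probe sets, of which 45 were bright, 27 of 34 for variable segments and 18 of 30 for constant regions or whole loci. The annotation gives Ighm 16 probe sets, of which 9 were bright, and their signals on array 1 ran from 12.6 to 56115.7. All 8 measured genes of MHC class I presentation were bright, with H2-K1 at 24113 ± 2411 (SD, n = 2), from a probe set marked for a family of sequences, and B2m at 15115 ± 578. Without probe sets marked for several targets 5 of 6 were bright, against 43.4% of all named genes. With the cutoff at the 75th percentile 5 of 8 were, against 28.5%. The embryonic globins Hba-x, Hbb-bh1 and Hbb-y gave 128 ± 22.7, 227 ± 20.4 and 94.9 ± 84.4 and were not bright, beside the adult Hba-a1 and Hbb-b2, which were. None (0) of 11 cytokines made by activated T cells was bright; Il2 gave 6.55 ± 0.495 and Ifng gave 9.85 ± 6.43. Among sex-linked transcripts, 1 of 4 was bright, the Y-linked Eif2s3y at 542 ± 58.4, read by a probe set marked for a family of sequences, while Kdm5d gave 41.4 ± 34.2, Uty gave 135 ± 19.4 and Xist gave 47.2 ± 18.5.

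The bright signals of pancreatic enzymes in spleen RNA are the pattern most worth a second look, and the tests with the serine proteases and with the B cell list were chosen after it was seen. RNA of an organ poor in B cells under the spleen label is argued against by the B cell list, at the 100th percentile. That list cannot tell spleen from another organ rich in B cells, or from a mixture that contains spleen. Cross-hybridisation among serine proteases as the whole cause is argued against by 4 members of the pattern that are not serine proteases. These were Cel, Clps, Pnliprp1 and Reg1, and 4 of 4 were bright. Carry-over of gut organs in general is argued against by 13 genes of stomach and intestine, at percentile 0.1 with 1 bright, Tff1. A candidate explanation is acinar pancreas RNA in the purchased spleen RNA, but a further list of 16 measured acinar genes, written before its values were seen, lay at the 70.95th percentile with 8 bright, among them Zg16 at 2484 ± 67.5, Sycn at 2245 ± 74.2 and Ctrl at 2989 ± 0.778. The 8 that were not bright were Cuzd1, Spink1, Reg3a, Reg3g, Rbpjl, Dnase1, Cckar and Nr5a2. Over the alternatives the percentile of this list ranged from 6.58 to 76.7. The lowest value came without probe sets marked for several targets, with 4 of 11 genes bright. That setting leaves out the probe sets that gave the bright values of Ctrl, Klk1, Reg3b and Pla2g1b. The probe set of Ctrl carries the suffix _r_at and that of Pla2g1b the suffix _i_at. The lower percentile is therefore not by itself evidence of signal from other targets. Acinar pancreas RNA therefore stays open as an explanation. Of 13 islet genes 0 were bright on both arrays, 1 on array 1 alone and 3 with both lower cutoffs; transcription of these enzymes by spleen cells was not tested, and no pancreas array was used here to say what share of RNA would be needed.

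A second pattern is that Rps14, Rps15, Rps20 and Rpl32 lay near the floor while the other 9 ribosomal protein genes were bright, although ribosomes need all of them. Probe sets that do not read the mature transcript may account for this. The test asked whether other probe sets of these genes were bright, and it decided nothing: the number was 0 because 0 of the 4 genes had another probe set. Low abundance of these 4 transcripts cannot be told apart from it here. The probe set of Rpl32 carries the suffix _r_at, and those of Rps14, Rps15 and Rps20 do not. For comparison, 383 of 2073 genes with several probe sets had 1 bright and 1 at or below the bacterial controls.

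A further pattern is that 3 of the 10 genes furthest apart between the arrays, Limk1, Junb and Rgs19, were read by probe sets with the suffix _r_at, which marks relaxed probe selection, against 2.89% of bright genes. With these 3 left out, 170 bright _r_at probe sets remained. Among them was 1 without a gene name and with a log2 difference of -1.08, and the pooled SD without it was not computed. The 170 had a pooled SD of 0.192, against a median of 0.149 for random sets matched on mean signal, at the 99.52nd percentile. This is consistent with lower repeatability of such probe sets. No biological explanation was tested, since both arrays came from RNA of 1 catalogue number.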
